A study of Homo sapiens with 6 samples.

How the data were processed

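Total RNA from 6 PANC1 samples, 3 with wild-type PGAM1 and 3 with PGAM1 K99R, was sequenced with standard Illumina libraries, per the labels' protocols. The authors deposited a table of FPKM (reads or fragments per kilobase of gene, scaled by depth) for each gene and library. The submitters' processing notes name GRCh38, Bowtie2 2.2.3, TopHat2, HISAT2 2.1.0 and HTSeq 0.6.0, with no role or order. The annotation release, the gene length definition, the strand setting and whether reads were paired are not given in the sources used here. The table has 27967 gene rows, none at 0 in all 6 libraries. Genes were named through their Ensembl identifiers, of which 27760 were in GENCODE 29, whose coordinates on GRCh38 are printed. For lack of a symbol, 5473 rows were named by the identifier alone.

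The depth was worked out from the deposited FPKM. With the union of exons in GENCODE 29 as gene length, 92.9% of values above 0 came out as whole reads within a tolerance of 0.01 reads. Reads were whole in all 6 libraries for 25967 genes. For 1786 more a length was solved from the values themselves at a wider tolerance, so whole reads there are no check of that length. Together these genes include 11369 of the 11552 genes tested (98.4%). Depth was 16795195 to 18018741 reads, a ratio of 1.073 between the deepest and the shallowest library. The reads recovered made up 91.7% to 91.9% of it. Read numbers printed for a gene are sums over the 3 libraries of a group and are left out where they were not recovered.

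Groups were taken from the sample labels. Genes with a mean of at least 1 FPKM over the 6 libraries were kept, 11552 in all (10096 protein coding), and log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided, Benjamini-Hochberg, threshold 0.05), with 4 residual and 3.59 prior degrees of freedom. No further scaling was applied. The median SE of a log2 fold change was 0.0557. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 36 of 43 lists with at least 5 kept members, and again with an estimated correlation, by ranks and with fry. Fry asks whether a list's genes move one way on balance and makes no comparison with other genes. Of the list entries, 863 were matched to the table and 77 were not in it or ambiguous. Folds of FPKM are ratios of group means, and log2 fold changes are on the log2(FPKM + 1) scale.

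The groups, tests, lists and most alternatives were fixed before the data were examined. So was the rule for named genes. It takes the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap, passing over rows without a symbol, together with the phosphoglycerate mutase family and ENO1, LDHA, PKM and PHGDH. It adds up to 4 members with the smallest p of each list that passed or has at least 3 members past the gene threshold, of which some are not reported here. ENO2 and KRT7 in marker lists, ENG, SPINK1 and CD14 were named after their values were seen. Alternatives changed the pseudocount, the filter, the scaling, the limma settings, the list test or the threshold, added a replicate block, or left out each library in turn. One, limma's voom on the recovered reads, was added after the data were seen.

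The fit was tested on simulated reads for 11411 genes, drawn from the means and depths of the K99R against wild-type comparison with a dispersion of 0.002. Of 50 genes changed at each size, 44% were called at 1.25-fold, 94% at 1.5-fold, 98% at 2-fold and 100% at 4-fold. Of 185 calls 17 were false, more than the threshold of 0.05 aims at. The changed genes were drawn above a higher minimum mean FPKM than that of the fit. They were also a far smaller share of all genes than the 59.3% that passed in the data. Both the called and the false shares depend on that share, so they do not carry over to the data. Of 40 simulated lists 1 was called, the raised one, and with an estimated correlation 1 list was called too. These lists held random genes simulated independently, so they cannot check camera on lists whose members are correlated. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the other steps, among them the exact permutation test.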

Results

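Gene expression was measured by RNA sequencing in PANC1, a human cell line derived from a carcinoma of the pancreatic duct. The cells had been stably depleted of their own PGAM1, the phosphoglycerate mutase of glycolysis, and then made to express either wild-type PGAM1 (3 libraries) or PGAM1 K99R (3 libraries), in which a lysine is replaced by an arginine. The comparison between the 2 groups asks which transcripts differ between cells carrying the wild-type and the K99R enzyme. Cells with unaltered PGAM1, or without a reconstituted copy, were not analysed here. The deposited values are FPKM per gene, and the steps between low values gave the depth behind them. It was 16950313, 17357251 and 17896571 reads for wild-type replicates 1 to 3, and 18018741, 18011499 and 16795195 reads for K99R replicates 1 to 3.

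The libraries of a group were close to each other. Across the 11552 genes with a mean FPKM of at least 1, Pearson's r between log2(FPKM + 1) profiles was 0.992 to 0.994 within groups and 0.964 to 0.968 between groups, where genes are not independent replicates. The mean chi-square per gene, which is 1 under counting noise alone, was 1.51 to 2.12 between wild-type libraries and 1.61 between K99R replicates 1 and 2. K99R replicate 3 stood apart from K99R replicates 1 and 2, at 4.995 and 5.08, against 55.6 to 58.6 for pairs from different groups. No pair agreed within counting noise, so each library was counted once. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

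PGAM1 itself (ENSG00000171314, chromosome 10 from 97426160 to 97433441 in GRCh38) was examined first. Its FPKM was 126.6, 124.5 and 124.6 in the wild-type libraries and 170.4, 174.4 and 170.0 in the K99R libraries. The means of 125.2 ± 1.16 and 171.6 ± 2.42 (SD, n = 3 each) make PGAM1 1.37-fold higher in K99R, with a log2 fold change of 0.45 (SE 0.03, limma adjusted p = 7.8e-06). A two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Gene-level values cannot separate transcripts of the depleted gene from those of the reconstituted copy, nor the wild-type from the K99R sequence, so these values do not show which form was expressed. PGAM1 also has near-identical pseudogenes, and 4 such rows held 30 reads in the wild-type and 56 in the K99R libraries, against 16788 and 23281 reads on PGAM1. How reads that map to several places were counted is not given, so these numbers cannot show that the PGAM1 value is unaffected.

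Within the phosphoglycerate mutase family, the 3 members above the expression filter all rose, also when adjusted over the list alone, a number too small for a list test. PGAM5, a mitochondrial phosphatase of this family, went from 12.95 ± 0.20 to 15.4 ± 0.50 FPKM (limma adjusted p = 0.00103). BPGM, the bisphosphoglycerate mutase, went from 7.12 ± 0.52 to 9.53 ± 1.18 FPKM (limma adjusted p = 0.00702). PGAM4, a retrocopy of PGAM1, was below the filter, with 0.6003 ± 0.195 and 0.596 ± 0.097 FPKM from 24 reads in each group. Among neighbouring enzymes fixed for reporting, PKM (pyruvate kinase) rose from 238.2 ± 1.12 to 315.7 ± 8.87 FPKM (limma adjusted p = 2.0e-05). LDHA (lactate dehydrogenase) had 354.2 ± 3.43 and 353.7 ± 14.4 FPKM (limma adjusted p = 0.952). ENO1 (enolase) rose 1.13-fold, from 923.5 ± 14.7 to 1045 ± 21.7 FPKM (limma adjusted p = 0.00119), a call that ended after quantile normalization (adjusted p = 0.091). PHGDH, which draws 3-phosphoglycerate into serine synthesis, moved further: it fell 1.96-fold, from 133.2 ± 1.44 to 67.96 ± 1.72 FPKM (SD, n = 3 each). Its log2 fold change was -0.96 (SE 0.03, limma adjusted p = 4.5e-07), and the gene lies on chromosome 1 from 119648411 to 119744226.

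**Figure D1:**
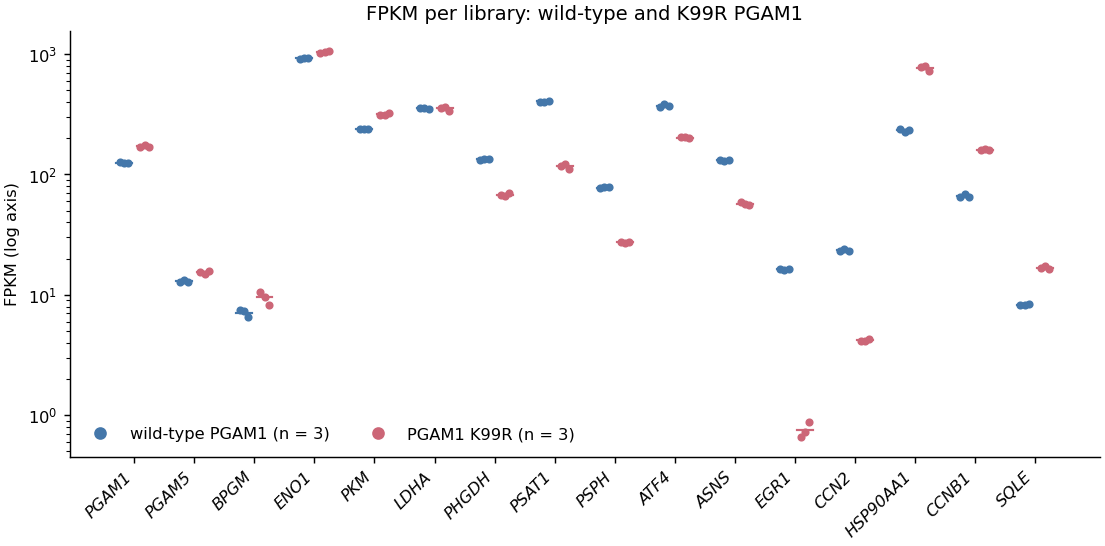
FPKM (log axis) of 16 genes in each of the 6 libraries, with wild-type PGAM1 in blue and PGAM1 K99R in red, where each point is a library and each bar the mean of 3. PGAM1 lay at 124.5 to 126.6 FPKM in wild type and 170.0 to 174.4 in K99R, and EGR1 had the widest gap of the genes drawn, with means of 16.4 and 0.751 FPKM.

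Of the 11552 genes tested, 6846 (59.3%) differed between the groups with limma at a Benjamini-Hochberg threshold of 0.05. They comprised 3429 higher and 3417 lower in K99R. Most differences were small. The median absolute log2 fold change of these genes was 0.325, and 77 genes were at least 2-fold higher and 170 at least 2-fold lower on the log2(FPKM + 1) scale. That scale understates the change of weakly expressed genes, and these counts were 141 and 300 with a pseudocount of 0.1, 120 and 262 on TPM, and 163 and 328 with voom on recovered reads. The 3 libraries of one group all lay above the 3 of the other for 7662 genes (66.3%), where chance gives 10%.

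The gene with the deepest fall among named genes was EGR1, an immediate early transcription factor on chromosome 5 from 138465490 to 138469315. It had 16.4 ± 0.13 FPKM with wild-type PGAM1 and 0.751 ± 0.111 with K99R (SD, n = 3 each), 21.8-fold lower, with a log2 fold change of -3.31 (SE 0.05, limma adjusted p = 8.5e-08). The other 9 genes of the 10 largest falls include secreted factors, receptors and metabolic genes. FGF21, a metabolic hormone, was 9.23-fold lower (7.32 to 0.793 FPKM), and INHBE, an inhibin subunit, 6.89-fold lower (11.9 to 1.72 FPKM). PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, dropped from 61.0 ± 0.78 to 12.2 ± 0.66 FPKM. CCN2, a matricellular protein, fell from 23.4 ± 0.54 to 4.21 ± 0.10 FPKM, and IL20RB, a cytokine receptor chain, from 44.2 ± 0.90 to 8.17 ± 0.36 FPKM. LAMP3 fell 5.57-fold, the netrin receptor UNC5B 4.88-fold and the long noncoding RNA LINC02970 6.04-fold. MT1E, a metallothionein, fell from 67.8 to 13.9 FPKM, a value made uncertain by near-identical family members.

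The largest rise by that rule was HSP90AA1, the inducible HSP90 chaperone gene on chromosome 14 from 102080738 to 102139699. It went from 233.1 ± 5.40 to 771 ± 37.3 FPKM (SD, n = 3 each), 3.31-fold higher, with a log2 fold change of 1.72 (SE 0.04, limma adjusted p = 1.9e-07). HSPB8, a small heat shock protein, rose 3.38-fold from 11.4 to 38.4 FPKM. KPNA2, a nuclear import receptor, rose from 88.9 ± 3.18 to 258.1 ± 2.57 FPKM. The keratin KRT17 rose from 43.3 to 125.6 FPKM, the zinc transporter SLC39A10 from 12.1 to 36.2 FPKM, and FGFBP1, an FGF binding protein, from 2.86 to 10.4 FPKM. AKR1C3, an aldo-keto reductase, rose from 11.7 to 34.8 FPKM, and it and KRT17 have close relatives that can share reads. HSP90AA2P rose 3.35-fold but is a pseudogene copy of HSP90AA1, so its reads may be those of the parent. The noncoding IGFL2-AS1 (4.11-fold) and FOXF2-DT (4.34-fold) also rose. Whether reads were counted by strand is not given in the sources used here, so reads of a gene on the opposite strand cannot be told apart from theirs.

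**Figure D2:**
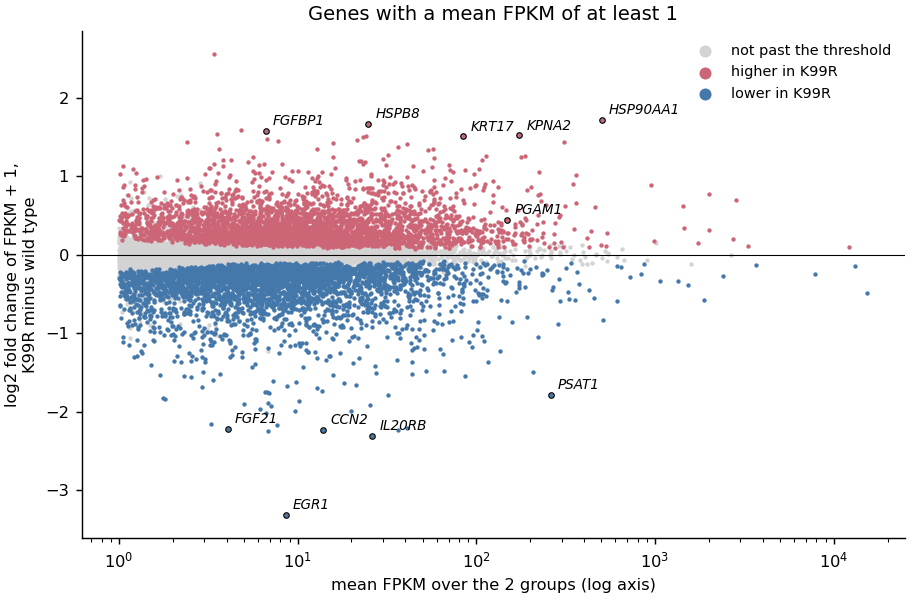
Log2 fold change of FPKM + 1 (K99R minus wild type) against the mean FPKM (log axis) for the 11552 genes tested, with 3429 genes higher in K99R in red, 3417 lower in blue and the rest in grey. EGR1 (-3.31) is the lowest point, the highest (2.56) is ENSG00000228873, passed over for lack of a symbol, and HSP90AA1 (1.72) stands out among abundant transcripts, while PGAM1 lies at 0.45.

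Gene lists fixed before the data were examined were tested with limma's camera, which asks whether a list moves apart from the other genes. Of 36 lists with at least 5 members, 15 passed an adjusted p of 0.05 with the preset inter-gene correlation of 0.01, with 5 higher and 10 lower in K99R. With an estimated correlation none of the 15 passed (11 of 36 lists had an unadjusted p under 0.05), and those p-values are given beside each of them. This correlation was above 0.01 for the G2 and M-phase (0.194), DNA repair (0.231), collagen (0.186), immediate early (0.235) and ERK feedback (0.093) lists. For the rest of the 15 it was negative, as in the heat shock list (-0.005), so correlation between members does not account for their loss. With this option camera also uses only the 4 residual degrees of freedom. Fry called 30 lists. Counts of members that rose or fell are adjusted over all genes, and adjusted over the list alone they were identical unless another count is given.

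Genes of serine synthesis and of the ATF4 response fell together. Of 14 serine, glycine and one-carbon genes, 10 fell, 1 rose and 3 did not pass (median log2 fold change -0.79, camera adjusted p = 0.00018, adjusted p = 0.078 with an estimated correlation). All 3 enzymes of the pathway from 3-phosphoglycerate to serine fell: PHGDH as above, PSAT1 from 404.8 ± 4.26 to 117.2 ± 5.52 FPKM and PSPH from 77.7 ± 0.56 to 27.2 ± 0.09 FPKM. The mitochondrial folate enzyme MTHFD2 fell from 61.5 ± 1.31 to 25.9 ± 0.93 FPKM. In the list for ATF4 and the unfolded protein response, 17 of 21 genes fell and 2 rose (median -0.75, camera adjusted p = 1.1e-06, adjusted p = 0.055 with an estimated correlation). ATF4, the transcription factor itself, dropped 1.84-fold, from 372.9 ± 9.30 to 202.8 ± 3.34 FPKM. ASNS (asparagine synthetase) fell from 131 to 57.3 FPKM, the pseudokinase gene TRIB3 from 129.6 to 44.0 FPKM and the stress gene NUPR1 from 21.7 to 5.84 FPKM. Among 16 glutamine and aspartate genes 9 fell and 4 rose (median -0.21, camera adjusted p = 0.019, adjusted p = 0.16 with an estimated correlation). Besides ASNS, which both lists hold, GPT2 (16.4 to 6.40 FPKM), ASS1 (300.4 to 144.9 FPKM) and the amino acid transporter SLC38A1 (90.7 to 49.9 FPKM) fell.

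Chaperone genes and G2 and M-phase genes rose. Of 19 heat shock and chaperone genes 18 rose and 1 did not pass (median 0.87, camera adjusted p = 4.0e-10, adjusted p = 0.055 with an estimated correlation). Besides HSP90AA1, HSPA8 rose from 239.9 ± 2.69 to 485 ± 6.82 FPKM, HSP90AB1 from 660.6 ± 5.89 to 1230 ± 20.8 FPKM, and the HSP90 co-chaperone STIP1 from 77.8 ± 0.84 to 143.3 ± 2.67 FPKM. Several of these genes have pseudogene copies that can share reads. Of 28 G2 and M-phase genes 27 rose and 1 did not pass (median 0.79, camera adjusted p = 2.4e-13, adjusted p = 0.13 with an estimated correlation). KIF20A, a mitotic kinesin, rose 2.60-fold from 31.8 ± 0.78 to 82.7 ± 1.23 FPKM, and CCNB1 (cyclin B1) 2.43-fold from 66.4 ± 2.45 to 161 ± 2.80 FPKM. UBE2C rose 2.16-fold and the kinase AURKA 2.14-fold. Of 26 S-phase genes 12 rose and 4 fell (camera adjusted p = 0.31), with RRM2 (47.1 to 78.6 FPKM), E2F1 and FEN1 higher and CDC45 (16.2 to 12.3 FPKM) lower. The difference between the S-phase list and the G2 and M-phase list was not tested. Of 23 DNA repair genes 14 fell and 2 rose (median -0.24, camera adjusted p = 0.0022, adjusted p = 0.38 with an estimated correlation). BRCA1 fell from 13.4 ± 0.24 to 6.94 ± 0.37 FPKM, XRCC2 from 10.8 to 5.47 FPKM, CHEK2 from 11.5 to 6.80 FPKM and FANCI from 18.5 to 13.8 FPKM.

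Most immediate early genes, ERK feedback genes and YAP targets fell. Of 18 immediate early genes 16 fell and 1 rose (median -0.47, camera adjusted p = 1.5e-05, adjusted p = 0.2 with an estimated correlation). After EGR1, the nuclear receptor NR4A1 fell from 16.6 ± 0.83 to 3.85 ± 0.36 FPKM, MYC from 205.1 ± 2.09 to 113.4 ± 5.70 FPKM and MAFF from 3.83 to 1.33 FPKM. Of 16 ERK pathway feedback genes 15 fell and 1 rose (median -0.63, camera adjusted p = 1.5e-05, adjusted p = 0.14 with an estimated correlation). PHLDA1 fell from 4.96 ± 0.16 to 0.863 ± 0.116 FPKM, the transcription factor ETV5 from 16.4 to 6.42 FPKM, the phosphatase DUSP5 from 8.55 to 2.56 FPKM and SPRED2 from 13.2 to 7.84 FPKM. Of 20 YAP and TEAD targets 16 fell and 3 rose (17 and 3 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 5.3e-05, adjusted p = 0.077 with an estimated correlation). Besides CCN2, CCN1 fell from 65.2 ± 0.18 to 30.1 ± 0.71 FPKM, AJUBA from 26.4 to 13.4 FPKM and the ectonucleotidase gene NT5E from 16.2 to 8.25 FPKM.

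Most cholesterol genes and NRF2 targets rose. Of 22 genes of the cholesterol biosynthesis list 17 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 1.8e-06, adjusted p = 0.055 with an estimated correlation). SQLE, the squalene epoxidase, rose 2.03-fold from 8.30 ± 0.12 to 16.8 ± 0.53 FPKM. FDFT1 rose from 20.9 to 33.7 FPKM and NSDHL from 14.7 to 24.1 FPKM. Of 22 NRF2 targets 14 rose and 3 fell (15 and 3 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 0.00043, adjusted p = 0.078 with an estimated correlation). AKR1C3 led, UGDH rose from 17.5 to 42.2 FPKM and TRIM16L from 32.1 to 58.1 FPKM, while the efflux pump gene ABCC3 fell from 30.0 ± 0.48 to 11.0 ± 0.63 FPKM. Of 30 autophagy and lysosome genes 15 rose and 3 fell (median 0.11, camera adjusted p = 0.029, adjusted p = 0.16 with an estimated correlation), a call that also ended after quantile normalization (adjusted p = 0.11) and with a minimum mean of 5 FPKM (adjusted p = 0.066). The members that rose include lysosomal enzymes and a proton pump subunit, CTSL (44.8 to 89.2 FPKM), GLA (26.7 to 49.8 FPKM) and ATP6V0D1 (6.60 to 11.0 FPKM), whereas ULK1, a kinase that starts autophagy, fell from 29.8 to 13.8 FPKM.

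Of 16 collagen and basement membrane genes 11 fell and 2 rose (median -0.25, camera adjusted p = 0.0093, adjusted p = 0.35 with an estimated correlation), among them LAMB1 (54.0 to 31.2 FPKM), COL12A1 (75.7 to 48.5 FPKM), COL5A1 (31.1 to 20.7 FPKM) and LAMA5 (46.1 to 24.0 FPKM). Of 20 p53 targets 10 fell and 1 rose (median -0.13, camera adjusted p = 0.027, adjusted p = 0.16 with an estimated correlation). GDF15 fell from 64.9 ± 1.55 to 22.2 ± 3.18 FPKM, the death receptor gene TNFRSF10B from 41.4 to 24.4 FPKM, AEN from 14.8 to 8.77 FPKM and PLK2 from 8.96 to 6.26 FPKM. The call for p53 targets ended with a minimum mean of 5 FPKM (adjusted p = 0.095). Of 23 interferon-stimulated genes 14 fell and 5 rose (median -0.26, camera adjusted p = 0.038, adjusted p = 0.17 with an estimated correlation). OASL fell 14.99-fold from 3.40 to 0.227 FPKM, IFIT2 from 4.03 to 1.07 FPKM, IFI44 from 2.27 to 0.399 FPKM and IFI35 from 12.7 to 8.02 FPKM. This call ended without K99R replicate 3 (adjusted p = 0.053) and with a minimum mean of 5 FPKM (adjusted p = 0.43).

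**Figure D3:**
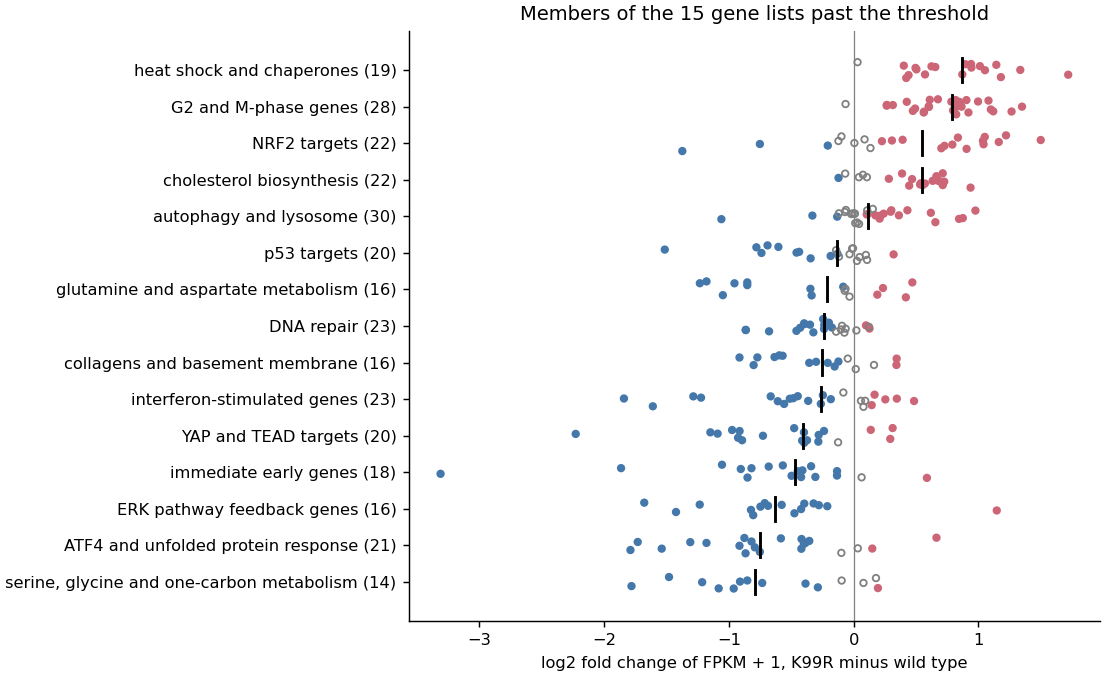
Log2 fold change of FPKM + 1 (K99R minus wild type) of each member of the 15 lists that passed, with the number of members in parentheses and a black bar at the median. Filled points passed the gene threshold (red higher, blue lower in K99R) and open points did not, and medians run from -0.79 for serine, glycine and one-carbon metabolism to 0.87 for heat shock and chaperones.

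Lists of central carbon metabolism moved in both directions. Of 23 glycolysis genes 11 rose and 9 fell (median 0.00, camera adjusted p = 0.72). The enolases ENO3 (7.74 to 16.3 FPKM) and ENO2 (5.62 to 8.89 FPKM) and the hexokinase HK1 (9.59 to 14.9 FPKM) rose, while the glucose transporter SLC2A3 fell from 13.7 ± 0.20 to 3.64 ± 0.43 FPKM. Of 9 pentose phosphate genes 4 rose and 2 fell (camera adjusted p = 0.68), with PRPS1, TKT and PGD higher and PGLS lower. In the tricarboxylic acid cycle 6 of 25 genes rose and 11 fell (12 adjusted over the list alone; camera adjusted p = 0.57), with SUCLG2 (18.3 to 9.78 FPKM), IDH1 (89.7 to 54.3 FPKM), DLST and PC lower. Of 34 nuclear genes of oxidative phosphorylation 8 rose and 8 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.83), NDUFA6 and NDUFS3 up and NDUFV1 and NDUFS1 down. Of 20 purine and pyrimidine genes 4 rose, among them IMPDH1, and 4 fell, among them GART (37.7 to 23.7 FPKM) and PAICS (camera adjusted p = 0.93). Of 14 fatty acid genes 3 rose and 6 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.55), with ACSL3, ACSS2, SCD and ACACA lower. For the glycolysis, pentose phosphate, tricarboxylic acid, purine and pyrimidine, mitochondrial and mesenchymal lists the median, the mean and the camera test differed in sign.

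Mitochondrially encoded transcripts held 25.4% to 26.8% of the FPKM total in wild-type libraries and 23.9% to 24.1% in K99R libraries. By reads their share of the depth was smaller, 8.69% to 9.26% in wild-type and 7.93% to 8.03% in K99R libraries. For the protein-coding mitochondrial transcripts alone the read shares overlapped, at 5.74% to 6.2% and 5.82% to 5.88%. Of the 15 mitochondrially encoded genes tested, ribosomal RNAs included, 6 rose and 5 fell (camera adjusted p = 0.98). MT-CYB rose from 1483 ± 54.5 to 2547 ± 60.2 FPKM. MT-ND6 rose from 1796 to 2232 FPKM and the ribosomal RNA MT-RNR1 fell from 1494 to 1182 FPKM. The other ribosomal RNA, MT-RNR2, fell from 17970 ± 595 to 12810 ± 142 FPKM. The calls for MT-ND6 (adjusted p = 0.071) and MT-RNR2 (adjusted p = 0.3) ended after quantile normalization, and that for MT-RNR2 also without a filter (adjusted p = 0.42).

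The remaining lists did not pass by the main test, though some did under other settings. Of 19 hypoxia and HIF-1 targets 10 fell and 4 rose (camera adjusted p = 0.066, or 0.0049 with a minimum mean of 5 FPKM, 0.021 on recovered reads and 0.045 without wild-type replicate 2), with STC2 (32.4 to 7.40 FPKM), VEGFA (15.9 to 6.29 FPKM) and PDK1 lower and P4HA2 higher. Of 18 integrin and matrix protease genes 12 fell and 4 rose (camera adjusted p = 0.062). ITGB4 fell 4.99-fold from 11.8 to 2.36 FPKM, ITGA2 from 6.06 to 2.31 FPKM and SERPINE2 from 23.2 to 11.8 FPKM, while TIMP3 rose. The integrin list passed after quantile normalization (adjusted p = 0.042), on recovered reads (adjusted p = 0.034), with a minimum mean of 0.1 FPKM (adjusted p = 0.034) and without a filter (adjusted p = 0.035). Of 27 actin cytoskeleton genes 15 rose and 6 fell (15 and 7 adjusted over the list alone; camera adjusted p = 0.088), with ACTG1, ACTB and ACTN4 higher, and the actins share reads with close copies. The actin list passed with a minimum mean of 0.1 FPKM (adjusted p = 0.033) and without a filter (adjusted p = 0.018). Of 10 antigen presentation genes 6 rose and none fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.091), HLA-E, TAP1, HLA-C and B2M among them, of which B2M lost its call after quantile normalization (adjusted p = 0.14). The antigen presentation list passed without a filter (adjusted p = 0.015) and, at an adjusted p that rounds to 0.05, with a minimum mean of 0.1 FPKM. Of 10 NF-kappaB targets and cytokines 7 fell and 2 rose (camera adjusted p = 0.099), BIRC3 and NFKB2 down and CCL2 and NFKBIA up. The list passed with a minimum mean of 0.1 FPKM (adjusted p = 0.018) and without a filter (adjusted p = 0.0056).

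Of 10 genes of the long noncoding RNA list 5 fell and 2 rose (camera adjusted p = 0.11, or 0.048 on recovered reads), with GAS5 (87.8 to 37.7 FPKM), NORAD (51.1 to 26.0 FPKM), SNHG1 and OIP5-AS1 lower. Of 11 epithelial genes 5 fell and 3 rose (camera adjusted p = 0.51): the claudins CLDN1 (32.6 to 9.64 FPKM) and CLDN7 (7.40 to 2.42 FPKM) and KRT7 fell, and KRT8 rose from 109.8 to 264.1 FPKM. Of 11 mesenchymal genes 3 rose and 3 fell (camera adjusted p = 0.99), VIM and TWIST1 up and CDH2 and ACTA2 down. Of 17 TGF-beta targets 7 rose and 8 fell (camera adjusted p = 0.85), with ID3 and SMAD6 higher and BHLHE40 and KLF10 lower. The Wnt list of 6 genes held 2 that rose, CD44 and DKK1, and 3 that fell, with MYC and CCND1 (2 and 4 adjusted over the list alone; camera adjusted p = 0.57). Of 11 histone genes 5 rose and 2 fell (camera adjusted p = 0.51), H2BC12, H2BC5 and H1-2 up and H1-4 down, in a family whose copies are nearly identical. Of 27 MYC targets and ribosome biogenesis genes 7 rose and 8 fell (6 and 7 adjusted over the list alone; camera adjusted p = 0.79), SRM, NOP2 and RRP9 up and NOLC1 down. Of 37 cytosolic ribosomal protein genes 12 rose and 6 fell (10 and 6 adjusted over the list alone; camera adjusted p = 0.57), with RPL3 and RPL12 lower and RPS19 and RPL18 higher.

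No acinar marker reached the filter, the highest being SPINK1 at a mean of 0.749 FPKM, and no leukocyte marker did, the highest being CD14 at 0.185 FPKM. The ductal list held 3 genes above the filter, of which KRT7 fell and the other 2 did not pass. The endocrine list held 2, of which ENO2 rose. The fibroblast list held 4, of which COL1A1 rose (11.3 to 14.7 FPKM) and FBLN1 and ACTA2 fell. The endothelial list held 1, ENG, which rose, at a mean of 25.3 FPKM. These lists had too few members for a list test.

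Other splits of the 6 libraries into 3 and 3 gave 4 to 10 lists by camera, against 15 for the real split. Each other split holds unequal numbers of wild-type and K99R libraries on its 2 sides, and so keeps part of the difference between groups. These counts therefore cannot show how often camera calls a list where there is no difference, and its error rate in these data stays unknown. The labels do not say whether each group is 1 stable cell population, and if so, a difference between the populations and one between the 2 forms of PGAM1 are the same contrast here. PGAM1 RNA was also 1.37-fold higher in K99R, so its amount and its form cannot be told apart either.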

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

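One alternative, voom on recovered reads, was chosen after seeing the data. The count of 6846 genes stayed within 1.5 times its value in the fits tried, with other pseudocounts, filters, scalings and limma settings, in which 67.6% (a minimum of 5 FPKM, with fewer genes tested) to 99.9% of its genes kept their call and direction. Leaving out 1 library gave 5966 to 6933 genes, 2993 to 3473 higher and 2972 to 3460 lower, 76 to 86 at least 2-fold higher and 163 to 189 at least 2-fold lower. It gave 14 to 16 lists, 5 higher and 9 to 11 lower, and a PGAM1 log2 fold change of 0.44 to 0.46. Samples share only a replicate number: the correlations of same-numbered deviations were 0.077, -0.056 and 0.077, wild-type replicates 1 and 2 correlated best with K99R replicates of another number, and with the replicate block 6724 genes passed. The interferon list lost its call under the block (adjusted p = 0.054).

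Counts of genes changed at least 2-fold were 141 higher and 300 lower with a pseudocount of 0.1, which shrinks changes of weak genes less than 1 does. They were 120 and 262 after rescaling to TPM, where a pseudocount of 1 is worth less because FPKM totals are 290386 to 294925, and 163 and 328 with voom, where the cause was not tested. With a minimum of 5 FPKM 2165 genes were lower and 102 at least 2-fold lower, with fewer genes tested. For lists, an estimated correlation left 0 past the threshold, 0 higher and 0 lower (11 at an unadjusted p under 0.05), while fry called 30, with 11 higher and 19 lower. Of named genes 3087 values kept their side of the threshold and 5 lost it, and of lists 740 kept it, 29 passed newly and 21 lost it, without a reversed direction among called results. At the depth, number of libraries and share of changed genes simulated, the smallest changes were called in 44% of 50 genes. Other depths and shares were not simulated.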

Other observations

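Further gene groups were chosen after the data were seen. Camera and fry p-values of these groups and of the further lists in the tests below were adjusted over these groups and lists alone. They were not adjusted over the 36 fixed lists, so they cannot be set against those of the fixed lists. Of 29 proteasome subunits 27 rose and 2 did not pass (28 rose adjusted over the list alone). The median log2 fold change was 0.356 (camera adjusted p = 3.4e-10, adjusted p = 0.025 with an estimated correlation), for example PSMD1 from 30.2 ± 0.91 to 56.8 ± 2.15 FPKM and PSMD3 from 43.0 to 75.8 FPKM. All 8 alpha and beta tubulin genes tested rose (median 0.84, camera adjusted p = 1.3e-06, adjusted p = 0.098 with an estimated correlation), with TUBB4B from 167.7 ± 4.39 to 454.8 ± 16.0 FPKM, although tubulins share reads between copies. The 3 metallothioneins above the filter fell, MT2A from 191.3 to 81.2 FPKM, MT1F from 2.49 to 0.839 FPKM and MT1E as above. Of 8 keratins, 3 of them also in fixed lists, 2 rose, KRT8 and KRT17, and 4 fell (camera adjusted p = 0.79, fry adjusted p = 0.034). Differences were seen within the K99R group too. RN7SL2, a signal recognition particle RNA named here for its spread, had 26.5, 15.7 and 57.6 FPKM in K99R replicates 1 to 3 and 8.94 to 10.4 FPKM in the wild-type libraries.

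Of the tests below, the one on scaling and the one on near-identical gene copies were chosen only after the result was seen. For the first pattern, the number of genes past the threshold, scaling was tested first. After quantile normalization, which ended the call of several abundant genes, 6804 genes still passed, so scaling of the libraries is not the whole cause. Median-ratio scaling gave 6845 genes but tests little. It hardly moved the values, with a median log2 fold change of all genes of -0.001 before and 0.0003 after. Gene length and GC content explained 2.87% of the variance of the log2 fold changes of these genes. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one with 6846, and the highest other gave 0 with limma (68 to 190 genes at an unadjusted p under 0.05, against 7352 for the real split). In each other split both sides hold wild-type and K99R libraries, so the difference between groups widens the spread within a side and lowers the count. For that reason, and because 10 splits are too few for a share under 0.05, the splits do not decide on chance. Whether K99R or a separate history of each stable cell population lies behind the difference cannot be told apart, since each group may be 1 population, and the correlation across genes of 0.047 between the difference within the K99R group (replicate 3 against 1 and 2) and that between groups does not decide it. The 1.37-fold higher PGAM1 RNA in K99R separates the same libraries, so its part cannot be told apart either.

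The second pattern was the fall of ATF4 and serine synthesis genes. A bias by gene length or GC content is argued against, since the median of the 35 members was -0.711 after its trend was subtracted and -0.751 before (SD of the members 0.626). The biological hypothesis that the ATF4 programme is less active in K99R cells was tested on aminoacyl-tRNA synthetase genes known as ATF4 targets and on the exportin XPOT. All 13 genes of this list fell, with a median of -1.05 (camera adjusted p = 2.0e-10, adjusted p = 0.025 with an estimated correlation), GARS1 from 168.7 ± 2.49 to 64.7 ± 1.48 FPKM, against a median of 0.038 for 8 other cytosolic synthetase genes. This is consistent with lower ATF4 activity as a hypothesis, while medium, density and the history of the cells stay open and untested.

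The third pattern was the rise of G2 and M-phase and of heat shock genes. Reads shared between near-identical copies are not the whole cause for the heat shock list: the 11 members without such copies, of which 10 rose, had a median of 0.572 (SD of the members 0.339), but the full list had 0.87 and the 8 members with copies 0.98, so part of the size and single genes such as HSPA1A and HSPA1B stay uncertain. Hypotheses on the cell cycle and on the heat shock factor HSF1 were tested on genes chosen outside these lists. For a larger share of cells in G2 or M phase, 25 of 26 further genes of these phases rose, with a median of 0.672 (camera adjusted p = 1.7e-11, adjusted p = 0.025 with an estimated correlation), which is consistent with it but could as well come from more transcript per cell. For higher HSF1 activity, 14 of 19 further targets and chaperonins rose and 2 fell, with a median of 0.451 (camera adjusted p = 8.8e-05, adjusted p = 0.098 with an estimated correlation), CCT3 from 166.6 to 286.9 FPKM, and 1 of the 19 also stands in a fixed list. No comparison set was chosen for these genes, so their rise does not tell HSF1 activity from another cause.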
